A study of Mus musculus with 15 samples.

How the data were processed

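Total RNA from sorted embryonic mouse thalamic cells was measured on Affymetrix expression arrays in 15 samples. The cells came from embryos on a C57BL/6 background that carried CreER and EGFP at the Gbx2 locus and a Cre-dependent tdTomato reporter at the Rosa26 locus. Pregnant females had received 4 mg tamoxifen at E9 for the E18.5 arrays and at E9.5 for the E14.5 arrays. Cells were sorted by fluorescence into red, green and double-labelled populations at E18.5 and into red and green populations at E14.5, with 3 biological replicates of each of the 5 groups. The labels do not give the sorting gates. Per the labels, RNA was extracted with a spin-column kit, 10 ng was amplified with the Nugen Ovation Pico WTA System V2, and the arrays were processed in Affymetrix Expression Console, for which no version or algorithm is stated.

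The values deposited by the authors were log2 signals per transcript cluster, between 4.15 and 13.2, and were used without a further transformation. The mean of all values lay between 6.17 and 6.19 in the 9 E18.5 arrays and between 5.63 and 5.65 in the 6 E14.5 arrays, a pattern that separate normalization of the stages would give. The labels do not say whether this was done. Levels set side by side across stages therefore carry that shift, which had a median of 0.60 for red and 0.61 for green cells. The number of arrays per group limits the precision of every value, and no depth applies to array signals.

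Gene symbols were those paired with the probes in the deposited table. Of 33794 transcript clusters, 23521 named 1 gene, 1814 named several and 8459 named none, and the 10273 in the last 2 classes were not used. By Entrez identifier, 23328 of the 23521 matched the mouse RefSeq annotation of assembly GRCm38.p6, which was used for names only and changed 0 symbols. The table held 22180 genes. For the 1082 with several transcript clusters, the cluster with the highest mean over the 15 arrays was used. The 25% of genes with the lowest mean, under 5.07, were left out, and 16635 genes were tested.

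All tests were made in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. A group-means model was fitted to all 15 arrays, with 10 residual degrees of freedom and 13.9 after empirical Bayes moderation. limma's moderated test was two-sided, and p was adjusted by Benjamini and Hochberg over the 16635 genes, with a threshold of adjusted p 0.05. The comparisons were red against green, double-labelled against green and double-labelled against red at E18.5, red against green at E14.5, E18.5 against E14.5 within red and within green cells, any difference among the 3 populations at E18.5 (moderated F), and the difference between stages of the red-green difference. Genes past the threshold in the same direction against both other E18.5 populations were counted as population-enriched. SDs are between the 3 arrays of a group, and SEs come from the model. By chance, a share of 0.05 of the 16635 genes would have an unadjusted p under 0.05.

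Gene groups were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 22 lists within each comparison. The lists were thalamic transcription factors, habenula, GABAergic and prethalamic neurons, glutamatergic transmission, neural progenitors, cell cycle, immature neurons, axon guidance, cadherins and protocadherins, ion channels, synaptic vesicle, retinoic acid, immediate early and stress genes, astrocytes, oligodendrocyte lineage, microglia, endothelial cells and pericytes, erythroid cells, meninges and choroid plexus, cortical excitatory neurons, hypothalamus with pretectum and zona limitans, and sex-linked genes. Members past the threshold were counted over all genes and adjusted over the list alone.

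The comparisons, the tests, the lists, the rule for named genes and the planned settings were chosen before the data were examined. The rule named Gbx2 in every comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with groups that did not overlap, and up to 4 members per list by smallest adjusted p. Symbols of predicted genes, clone names, micro- and nucleolar RNAs, olfactory and vomeronasal receptors, immunoglobulin and T-cell receptor segments and pseudogenes were left out of naming. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named. Up to 8 genes per population and direction were named for enrichment, and 5 per direction for the difference between stages. In E18.5 red against green, 1 gene that the rule names was not used here. After the values were seen, list members named for a comparison were narrowed to those past the threshold, and in the comparisons between stages to those past it both as deposited and after quantile normalization.

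Arrays with the same replicate number were checked for pairing by correlating their deviations from group means. Within E18.5, red and double-labelled arrays of the same number correlated at 0.487 to 0.669, so the value with replicate number as a block is given for that comparison. Correlations reached from 0.0583 to 0.465 for red with green, from 0.0474 to 0.414 for green with double-labelled, and from 0.0687 to 0.265 at E14.5, and those comparisons were not treated as paired. Even so, 8 of 9 E18.5 arrays and 6 of 6 E14.5 arrays correlated best, on average, with arrays of their own number in other groups. Pairing is therefore not excluded for those comparisons, and counts with a block are given beside them. The named genes, lists, population-enriched genes and leave-one-out fits come from the fit without a block, also for red and double-labelled cells.

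Other settings tried were no filter on dim genes, a filter at the median, quantile normalization, centring each array on its median, the mean of a gene's transcript clusters, a trended and robust fit, array weights, a fit to the compared arrays only, replicate number as a block, a 2-fold minimum, and leaving out each array in turn. Chosen after seeing the data were leaving out 2 E18.5 arrays with a narrow range of values, 1 weight per stage, and fits to the E18.5 arrays alone.

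The model was tested on simulated data with the spread of these arrays and 16635 genes. For E14.5 red against green it called 26.0% of genes changed 1.41-fold, 77.3% of those changed 2-fold and 97.9% of those changed 4-fold, and 2.76% of its calls were false. For E18.5 red against green the shares were 28.1%, 81.2% and 96.7%, and 30.9% of the calls were false, because the fit shares 1 spread between stages while the median within-group SD of a gene was 0.218 at E18.5 and 0.122 at E14.5. With 1 weight per stage the false share at E18.5 was 14.0% with 66.3% of 2-fold changes called, and with the 9 E18.5 arrays alone it was 5.88% with 55.5% called. In these sets genes and arrays varied independently, and all arrays of a stage shared the same spread. The false share also depends on how many genes were changed, so it compares settings and does not measure the share in the real calls.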

Results

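Gene expression was profiled in sorted thalamic cells of mouse embryos on 15 arrays, 3 biological replicates for each of 5 groups. EGFP and a tamoxifen-inducible Cre were expressed from the Gbx2 locus, so that green fluorescence reported this thalamic homeodomain factor and red fluorescence (tdTomato) marked the descendants of cells in which Cre was active after tamoxifen. Red, green and double-labelled cells were sorted at E18.5, and red and green cells at E14.5. Levels are log2 signals as deposited, given as mean ± SD of 3 arrays. In E18.5 red replicate 1 and double-labelled replicate 1 the SD of all values was 1.34 and 1.31, against 1.44 to 1.51 in the other 7 E18.5 arrays. These 2 arrays correlated with their group mates at 0.919 and 0.920, the other E18.5 arrays at 0.944 to 0.985 and the E14.5 arrays at 0.981 to 0.990. They are called the narrow-range arrays below.

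Red and green cells at E18.5 were compared to find genes that differed between thalamic populations late in gestation. Th, the rate-limiting enzyme of catecholamine synthesis, was 4.03-fold higher in red cells (8.05 ± 0.17 against 6.04 ± 0.14, n = 3) and Slc6a3, the dopamine transporter, was 4.08-fold higher (7.90 ± 0.25 against 5.87 ± 0.03). Aldh1a1, a retinaldehyde dehydrogenase, was 5.68-fold higher (8.99 ± 0.44 against 6.49 ± 0.28). Green cells had higher Calb2, which encodes the calcium-binding protein calretinin, by 5.30-fold (9.93 ± 0.32 against 7.53 ± 0.30), and higher Gbx2 by 4.21-fold (8.43 ± 0.17 against 6.35 ± 0.86). Since EGFP came from the Gbx2 locus, the sort itself favours lower Gbx2 in red cells. That difference is no independent finding, also where Gbx2 counts as a list member. Adjusted p was 4.7e-07 for Th, 1.1e-05 for Slc6a3, 2.2e-05 for both Aldh1a1 and Calb2, and 0.0052 for Gbx2. Red cells also had higher Cck (log2 difference 1.84), a neuropeptide, the vesicular monoamine transporter Slc18a2 (1.68), the nicotinic receptor subunit Chrnb3 (1.65), Cpne8 (1.54), the neuropeptide precursor Vgf (1.42), the nuclear receptor Nr4a2 (1.26) and the junctional adhesion molecule Jam2 (1.26). Lower in red cells were Clybl (-2.35), Nek7 (-2.24), the zinc finger factor Zic5 (-2.08), the LIM-domain cofactor Ldb2 (-2.0), Car8 (-1.90), the myosin light chain kinase Mylk (-1.63) and the zinc finger factor Plagl1 (-1.45). Other transcript clusters of Gbx2 and Plagl1 differed by -0.80 and -0.40.

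Thalamic transcription factors as a group were lower in E18.5 red than green cells, with a median log2 difference of -0.43. Of 16 tested, Gbx2 and Lhx9 (-0.99), a LIM-homeodomain factor, passed over all genes, and 9 lower and 1 higher passed adjusted over the list alone (camera adjusted p 3.9e-05, and adjusted p = 0.245 with an estimated correlation). GABAergic and prethalamic genes were higher by a median of 0.14, with Sp9 (0.88), a zinc finger factor, past the threshold out of 17 and 2 adjusted over the list alone (camera adjusted p 6.0e-04, and adjusted p = 0.274 with an estimated correlation). Immediate early and stress genes were higher by a median of 0.24, with 0 of 13 past limma's threshold over all genes, 5 at unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p 0.0020, and adjusted p = 0.274 with an estimated correlation). The list of hypothalamus, pretectum and zona limitans was higher by 0.14, with the forkhead factor Foxa1 (1.18) alone past the threshold of 10, also adjusted over the list alone (camera adjusted p 0.0066, adjusted p = 0.471 with an estimated correlation, and 0.117 at the preset correlation after quantile normalization). Neural progenitor genes were higher by 0.10, with 0 of 15 past limma's threshold, 4 at unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p 0.025, adjusted p = 0.471 with an estimated correlation, and 0.065 at the preset correlation after quantile normalization). Camera called these 5 lists, 3 without the narrow-range arrays and 8 without green replicate 2. Adjusted p was from 0.10 to 0.647 for the other 17 lists, among them those of astrocytes, the oligodendrocyte lineage, microglia, endothelial cells with pericytes, erythroid cells, and meninges with choroid plexus. Within them, Chrnb3 and Nr4a2 passed of 10 habenula genes, the axon guidance cues Ntn1 (0.63) higher and Sema3a (-0.52) and Flrt1 (-0.96) lower of 47 axon guidance genes, Slc18a2 higher and the synapsin Syn2 (-1.10) lower of 18 synaptic vesicle genes, and Aldh1a1 of 14 retinoic acid genes. Median, mean and camera direction did not share a sign for glutamatergic transmission, cell cycle and synaptic vesicle genes.

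In E18.5 red cells 44 genes were higher and 58 lower than in green cells by limma, 102 in all, 46 of them by at least 2-fold, and 1666 genes had an unadjusted p under 0.05. All 102 had groups that did not overlap, as did 15.3% of all genes. Chance gives 10% in independent arrays, and gave a mean of 6.53% in 20 simulated sets with arrays of the same number correlated as observed. The count was 213 without the narrow-range arrays, 51 without green replicate 1, 52 without green replicate 2 and 60 without green replicate 3. It was 44 with 1 weight per stage, 12 with the 9 E18.5 arrays alone, 46 with these but not the narrow-range arrays and 6 with the 6 compared arrays alone. With replicate number as a block more genes passed, 101 of the 102 among them. In simulated data 30.9% of calls in this comparison were false, a mean of 61.2 calls per set. That share depends on how many genes were changed in the simulation and is no estimate for the 102 genes. Of the 26 named genes past the threshold, 16 kept their call whichever array was left out. Car8, Plagl1, Sp9, Sema3a, Ntn1, Syn2, Slc18a2, Cpne8, Cck and Zic5 lost theirs at least once, 10 of them without green replicate 1, 8 without green replicate 2, 6 without green replicate 3 and 6 without each red array, at an adjusted p of at most 0.217.

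Double-labelled cells at E18.5 were compared with green cells to find what distinguished the EGFP-expressing cells that also carried the tdTomato mark. Vgf was 2.49-fold higher in double-labelled cells (9.44 ± 0.14 against 8.12 ± 0.12, adjusted p 0.0043) and Ebf1, a helix-loop-helix transcription factor, 2.37-fold higher (8.23 ± 0.13 against 6.98 ± 0.36, adjusted p 0.017). Igfbp4, a binding protein for insulin-like growth factors, was 2.07-fold higher (adjusted p 0.030), and Pou2f2, a POU-domain factor, 1.99-fold higher (adjusted p 0.033). Smarca2, an ATPase of chromatin remodelling complexes, was 2.18-fold lower (8.21 ± 0.26 against 9.33 ± 0.17, adjusted p 0.030) and Grpr, the gastrin-releasing peptide receptor, 1.80-fold lower (6.18 ± 0.06 against 7.03 ± 0.20, adjusted p 0.031). Gbx2 stood at 8.33 ± 0.29 in double-labelled and 8.43 ± 0.17 in green cells (adjusted p 0.938). Next by p but not past the threshold were Cntnap5b (log2 difference 1.07, adjusted p 0.056), Insyn2a (-0.68, 0.070), Wif1 (-0.81, 0.138) and Prkg1 (-0.62, 0.138).

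No gene list had a member past limma's threshold over all genes in this comparison (0 of 16 thalamic transcription factors, with 6 at unadjusted p under 0.05). Adjusted over the list alone, 5 thalamic transcription factors were lower in double-labelled than in green cells, and camera called that list down (median -0.10, adjusted p 0.0050, and adjusted p = 0.492 with an estimated correlation). Camera also called axon guidance (adjusted p 0.026) and immature neuron genes (0.049) lower, and hypothalamic, pretectal and zona limitans (0.0085), GABAergic and prethalamic (0.026) and immediate early and stress genes (0.026) higher, with adjusted p from 0.492 to 0.619 with an estimated correlation for the 6 lists. Camera called 2 lists without green replicate 1 and 2 without double-labelled replicate 1, 0 after quantile normalization and 0 without the narrow-range arrays. The other 16 lists had an adjusted p from 0.068 to 0.436.

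Limma called 6 genes between double-labelled and green cells, 4 higher and 2 lower, and 949 genes had an unadjusted p under 0.05. Groups did not overlap for 8.15% of all genes, where chance gives 10% in independent arrays and 6.91% in the correlated simulated arrays. The count was 35 without the narrow-range arrays and 12 with replicate number as a block. It was 0 with 1 weight per stage, with the 9 E18.5 arrays alone, with these but not the narrow-range arrays and with the 6 compared arrays alone. It was 2 without green replicate 1, 3 without green replicate 2, 0 without green replicate 3, 2 without double-labelled replicate 1, 1 without double-labelled replicate 2 and 8 without double-labelled replicate 3. None of the 6 genes kept its call in all 6 fits without 1 of these arrays, with adjusted p up to 0.176, reached without green replicate 1, and after quantile normalization Pou2f2 (adjusted p 0.15) and Smarca2 (0.13) no longer passed.

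Double-labelled and red cells at E18.5 shared the tdTomato mark, and their comparison asked what differed with EGFP. Gbx2 was 3.93-fold higher in double-labelled cells (8.33 ± 0.29 against 6.35 ± 0.86, adjusted p 0.018), as were Calb2 at 2.85-fold (9.04 ± 0.08 against 7.53 ± 0.30, adjusted p 0.0047), the neuromedin B receptor Nmbr at 2.87-fold (6.84 ± 0.42 against 5.32 ± 0.17, adjusted p 0.0047) and Ldb2 at 3.22-fold (10.07 ± 0.35 against 8.39 ± 0.63, adjusted p 0.016). The sort on EGFP favours the Gbx2 difference here as well. Aldh1a1, Th, Chrnb3, Slc6a3 and Nr4a2, which were higher in red than in green cells, were also higher in red than in double-labelled cells, while Slc18a2 did not pass here (log2 difference -0.62). Aldh1a1 was 5.24-fold lower in double-labelled cells (6.60 ± 0.21 against 8.99 ± 0.44, adjusted p 7.0e-05), Th 3.29-fold lower (6.33 ± 0.03 against 8.05 ± 0.17, adjusted p 3.8e-06), Chrnb3 3.12-fold lower (5.13 ± 0.28 against 6.77 ± 0.23, adjusted p 7.0e-05) and Slc6a3 2.88-fold lower (6.37 ± 0.17 against 7.90 ± 0.25, adjusted p 2.0e-04). Also lower were the metalloprotease Tll1 (log2 difference -1.52), Nr4a2 (-1.13), the AMPA receptor accessory subunit Gsg1l (-0.94), the zinc finger homeobox factor Zfhx4 (-0.92), the phosphatase Inpp4b (-0.77) and the aromatic amino acid decarboxylase Ddc (-0.77). Cntnap5b was next among the higher genes without passing (0.98, adjusted p 0.057).

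Of 10 habenula genes Chrnb3 and Nr4a2 passed, also adjusted over the list alone, and camera called the list lower in double-labelled than in red cells (median -0.04, adjusted p 0.0012, and adjusted p = 0.123 with an estimated correlation). It was the 1 list called, against 2 lists without red replicate 1, 3 without red replicate 2, 3 without red replicate 3, 3 without double-labelled replicate 1 and 2 without double-labelled replicate 3. Among 16 thalamic transcription factors Gbx2 passed, and 5 higher and 1 lower did so adjusted over the list alone (camera adjusted p 0.124). Of 14 retinoic acid genes Aldh1a1 passed. The other 21 lists had a camera adjusted p from 0.124 to 0.966, and median, mean and camera direction did not share a sign for cell cycle, immature neuron, synaptic vesicle, endothelial with pericyte, and hypothalamus with pretectum genes.

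Limma called 15 genes, 4 higher and 11 lower in double-labelled than in red cells, and 752 had an unadjusted p under 0.05. With replicate number as a block, which the paired structure of these groups calls for, 32 genes passed, including all 15, and 32 passed after quantile normalization. The fold changes, adjusted p, lists and leave-one-out calls given for this comparison come from the fit without the block. Groups did not overlap for 4.18% of all genes, where the correlated simulated arrays gave 4.17% and independent arrays would give 10%. The count was 39 without the narrow-range arrays (25 higher and 14 lower, the reverse of the balance as reported) and 7 without double-labelled replicate 2. It was 8 with 1 weight per stage, 4 with the 9 E18.5 arrays alone, 0 with these but not the narrow-range arrays and 0 with the 6 compared arrays alone. Of 14 named genes past the threshold 6 kept their call whichever array was left out. Tll1, Zfhx4, Ddc, Gsg1l, Ldb2, Gbx2, Nr4a2 and Inpp4b lost theirs at least once, 7 of them without double-labelled replicate 2, 5 without double-labelled replicate 3, 4 without red replicate 2, 3 each without red replicate 1 and red replicate 3, and 2 without double-labelled replicate 1, at an adjusted p of at most 0.181 (Ddc without double-labelled replicate 3).

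The 3 E18.5 populations were then compared together to find genes particular to 1 of them. Red cells had 9 genes higher than in both other populations: Aldh1a1, Th, Chrnb3, Slc6a3, Nr4a2, Gsg1l, Zfhx4, Inpp4b and Ddc, with the smaller difference from 5.24-fold for Aldh1a1 to 1.70-fold for Ddc. Gbx2, Ldb2, Calb2 and Nmbr were lower in red cells than in both others, by at least 3.93, 3.22, 2.85 and 2.42-fold. For Gbx2 the sort on EGFP, which came from its locus, favours this difference by itself. Green cells had higher Smarca2 (9.33 ± 0.17, against 8.21 ± 0.26 in double-labelled and 8.17 ± 0.30 in red cells) and higher Grpr, and lower Vgf, Ebf1 and Pou2f2, than both others. For double-labelled cells 0 genes were higher and 0 lower by limma than in both others, in the fit without a block. Their comparisons with green and red cells had 949 and 752 genes at an unadjusted p under 0.05. By chance a share of 0.05 of the 16635 genes would have such a p, so these counts by themselves are no sign of further differences. Limma's F test called 71 genes as differing among the populations, with 1208 at an unadjusted p under 0.05.

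The number of population-enriched genes was 18, against a mean of 0.25 and at most 2 in 20 simulated sets of arrays with no differences, in which arrays of the same replicate number were correlated as observed. In these sets genes varied independently and all arrays of a stage shared the same spread, so they held no narrow-range arrays. They do not measure chance for the real arrays, of which other regroupings gave up to 884. The observed number was 45 without the narrow-range arrays (1 of them, Cntnap5b, higher in double-labelled cells, while Ddc was no longer among those higher in red cells), 38 with replicate number as a block, 11 without green replicate 3 and 7 without double-labelled replicate 2. It was 8 with 1 weight per stage, 4 with the 9 E18.5 arrays alone and 0 with these but not the narrow-range arrays. The F-test count was 206 without the narrow-range arrays, 17 without green replicate 1, 27 without green replicate 2, 33 without green replicate 3 and 166 without double-labelled replicate 1. It was 16 with 1 weight per stage, 6 with the 9 E18.5 arrays alone and 21 with these but not the narrow-range arrays.

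Red and green cells at E14.5 were compared to ask the same of thalamic cells at an earlier stage. Green cells had higher Olig3, a basic helix-loop-helix factor of thalamic progenitors, by 9.10-fold (8.93 ± 0.29 against 5.75 ± 0.34, n = 3, adjusted p 8.9e-07), and higher Nhlh1, a helix-loop-helix factor of newborn neurons, by 5.76-fold (7.41 ± 0.46 against 4.89 ± 0.28, adjusted p 1.1e-05). The axonal repellent Slit2 was 5.51-fold higher in green cells (8.98 ± 0.21 against 6.52 ± 0.13, adjusted p 1.6e-06). Red cells had higher Grik3, a kainate receptor subunit, by 4.39-fold (9.00 ± 0.16 against 6.87 ± 0.70, adjusted p 2.9e-04), and higher Slc18a2 by 3.78-fold (9.97 ± 0.14 against 8.06 ± 0.81, adjusted p 0.0034). Also higher in green cells, as negative log2 differences of red from green, were the calcium-binding protein Calb1 (-2.97), Clybl (-2.61), the tubulin Tuba1c (-2.52), the Wnt pathway agonist Rspo3 (-2.52), the peroxisomal transporter Abcd2 (-2.19), the semaphorin receptor Nrp2 (-2.15) and the mitotic ubiquitin-conjugating enzyme Ube2c (-2.12). Higher in red cells were the phosphodiesterase Pde7b (2.19), Galntl6 (2.13), Kit ligand Kitl (1.96), the nuclear envelope protein Syne1 (1.94), the adhesion molecule Ncam2 (1.86), the channel Trpm3 (1.80), the splicing regulator Rbfox1 (1.80) and the synaptic adhesion molecule Lrfn5 (1.78). Gbx2 stood at 7.30 ± 0.03 in red and 8.07 ± 0.17 in green cells (adjusted p 0.271). Syne1 has many transcript clusters, and the others differed by 0.05 to 1.71.

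**Figure D1:**
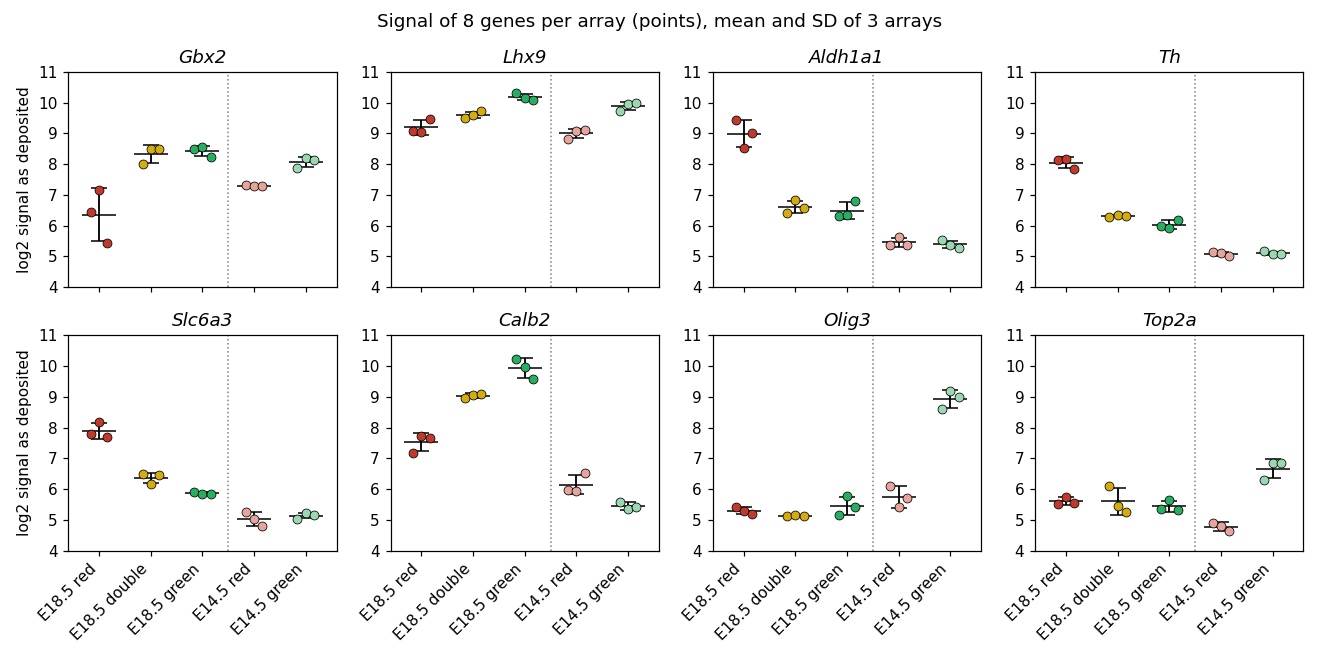
Log2 signal as deposited (y axis) of Gbx2, Lhx9, Aldh1a1, Th, Slc6a3, Calb2, Olig3 and Top2a in the 5 groups (x axis); points are single arrays, bars are means and error bars are SD (n = 3 per group). Aldh1a1 averaged 8.99 in E18.5 red cells against 6.49 in E18.5 green cells, and Olig3 averaged 8.93 in E14.5 green cells against 5.75 in E14.5 red cells; the E18.5 and E14.5 arrays sit on scales whose means differ.

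Cell cycle genes as a group were lower in E14.5 red than green cells. Of 14 tested, 8 passed over all genes and 8 adjusted over the list alone, with a median of -0.64 (camera adjusted p 4.4e-10, and adjusted p = 0.012 with an estimated correlation), among them the topoisomerase Top2a (-1.89), the mitotic kinase Cdk1 (-1.20), the proliferation marker Mki67 (-1.17) and the kinetochore protein Cenpf (-0.92). Of 27 ion channel genes 7 were higher in red cells, 12 adjusted over the list alone, with a median of 0.34 (camera adjusted p 4.8e-10, and adjusted p = 0.038 with an estimated correlation), such as the calcium channel Cacna1e (1.21) and the potassium channel Kcnj6 (1.06). Of 13 genes of glutamatergic transmission 4 were higher, the receptor genes Grm5 (1.58), Grin2b (1.03), Gria1 (0.88) and Gria4 (0.72), and 7 adjusted over the list alone, with a median of 0.53 (camera adjusted p 9.3e-06, and adjusted p = 0.038 with an estimated correlation). Another transcript cluster of Grin2b differed by 0.23.

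Synaptic vesicle genes were higher in E14.5 red cells by a median of 0.28, with Slc18a2, Syt1 (0.92) and Stx1a (0.69) past the threshold of 18, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p 4.0e-04, and adjusted p = 0.258 with an estimated correlation). GABAergic and prethalamic genes were higher by 0.13, with Gad2 (0.82), a glutamate decarboxylase, and Meis2 (0.81) past it of 17 and 3 adjusted over the list alone (camera adjusted p 4.3e-04, and adjusted p = 0.189 with an estimated correlation). Cadherins and protocadherins were higher by 0.28, with Cdh11 (1.14), Pcdh7 (1.12) and Cdh4 (0.95) higher and Pcdh8 (-0.82) lower of 22, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p 0.0013, and adjusted p = 0.690 with an estimated correlation). Another transcript cluster of Cdh4 differed by 0.25. Of 3 erythroid genes the embryonic globin Hbb-y was higher in red cells (1.46; 6.61 ± 0.51 against 5.15 ± 0.09), 2 passed adjusted over the list alone, and the list had a camera adjusted p of 0.0029, and adjusted p = 0.110 with an estimated correlation. Camera called these 7 lists. Members of other lists moved both ways. Rora (1.06), a nuclear receptor of thalamic neurons, was higher and Lhx9 (-0.89) and Lhx2 (-1.03) were lower among thalamic transcription factors, and the glial glutamate transporter Slc1a3 (1.01) was higher and Olig3 and the intermediate filament gene Nes (-0.54) were lower among neural progenitor genes. Of 47 axon guidance genes 5 were higher and 8 lower, 7 and 11 adjusted over the list alone, including Sema6d (1.01) and Slit1 (-0.98). Lower as well were Nhlh1, Igfbpl1 (-0.95) and Neurod1 (-0.63) of 15 immature neuron genes, Crabp1 (-1.17) of 14 retinoic acid genes, Btg2 (-1.50) of 13 immediate early and stress genes, Slc1a2 (-0.79) of 11 astrocyte genes and Foxa1 (-0.73) of 10 genes of hypothalamus, pretectum and zona limitans. The other 15 lists had a camera adjusted p from 0.070 to 0.982, and median, mean and camera direction did not share a sign for habenula, axon guidance (median 0.06, mean -0.09), oligodendrocyte lineage, cortical neuron, and hypothalamus with pretectum genes.

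**Figure D2:**
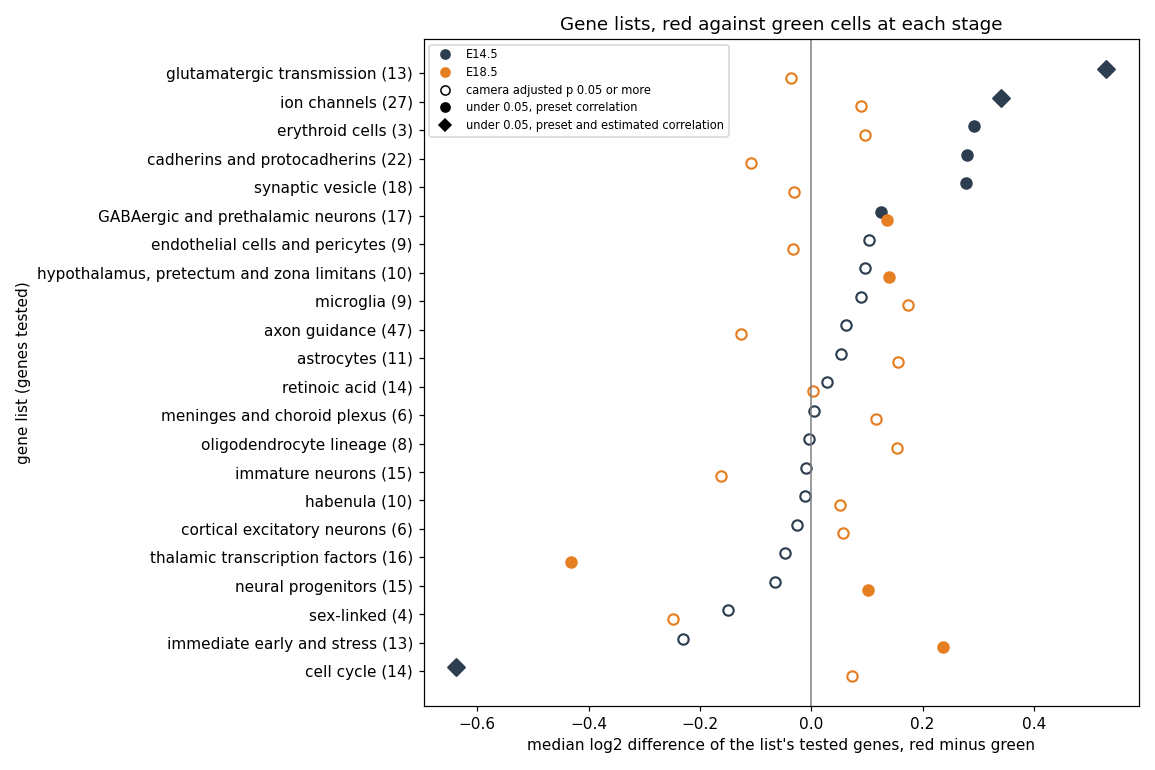
Median log2 difference, red minus green, of each gene list (x axis) for the 22 lists (y axis) at E14.5 (dark) and E18.5 (orange); filled marks had a camera adjusted p under 0.05 at the preset correlation, and diamonds also with an estimated correlation. Cell cycle genes had a median of -0.64 at E14.5, and thalamic transcription factors one of -0.43 at E18.5.

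At E14.5 limma called 586 genes, 314 higher and 272 lower in red than in green cells, 173 of them by at least 2-fold, and 1983 genes had an unadjusted p under 0.05. Groups did not overlap for 27.9% of all genes, where chance gives 10% in independent arrays and 7.90% in the correlated simulated arrays. The count was 1434 without the narrow-range E18.5 arrays and 1367 with the 6 compared arrays alone, and 324 without red replicate 1, 315 without red replicate 2, 272 without green replicate 2 and 247 without green replicate 3. With replicate number as a block, 569 of the 586 were called again. Of the 54 named genes past the threshold 37 kept their call whichever array was left out. Tuba1c, Meis2, Gad2, Gria4, Gria1, Nes, Neurod1, Pcdh8, Pcdh7, Cacna1d, Crabp1, Slc1a2, Foxa1, Cacna1c, Syne1, Cdh11 and Lhx2 lost theirs at least once: 16 without green replicate 3, 14 without green replicate 2, 13 without red replicate 1, 10 without red replicate 2, 3 without red replicate 3 and 2 without green replicate 1, at an adjusted p of at most 0.230. After quantile normalization Lhx2 (adjusted p 0.071) and Stx1a (0.074) no longer passed, nor did Cacna1c (0.98, adjusted p 0.011 as deposited and 0.080 after it) or Cacna1d (1.12, adjusted p 0.015 and 0.060).

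The next question was whether the red-green difference itself differed between the stages. Tamoxifen was given at E9 for the E18.5 arrays and at E9.5 for the E14.5 arrays. Double-labelled cells were sorted apart only at E18.5. Age can therefore not be separated from labelling day or from the way the cells were sorted. The stages lay on scales that differed by a median of 0.60 in red and 0.61 in green cells, and the median over all genes of the difference between stages was -0.0083. Calb2, at 5.46 ± 0.12 in E14.5 green cells and 9.93 ± 0.32 in E18.5 green cells, had a red-green difference that was lower at E18.5 by 8.52-fold (log2 -3.09 ± 0.27 SE, adjusted p 9.9e-05). The difference of Aldh1a1 was higher at E18.5 by 5.47-fold (2.45 ± 0.28 SE, adjusted p 6.0e-04), with 5.45 ± 0.14 in red and 5.40 ± 0.12 in green cells at E14.5. Olig3 (3.04 ± 0.27 SE, adjusted p 9.9e-05), Nhlh1 (2.49), Tuba1c (3.55) and the POU-domain factor Pou3f2 (2.32) were lower in red than green cells at E14.5 and did not pass at E18.5, so their difference was higher at E18.5. The differences of Ripor2 (-2.45), the AMPA receptor accessory subunit Cacng3 (-2.40), the kinase Mast4 (-2.39) and the calcium-binding protein Necab1 (-2.24) were lower at E18.5. Jam2 and Foxa1 were higher in red cells at E18.5 and lower at E14.5, and Cacng3 and Necab1 the reverse. For Gbx2 the difference between stages was -1.30 (adjusted p 0.241). Another transcript cluster of Mast4 differed between red and green cells by 1.08 at E14.5 and -0.48 at E18.5, against 1.56 and -0.83 for the one used.

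Cell cycle genes had a higher red-green difference at E18.5 than at E14.5, with a median of 0.66. Higher and lower in this paragraph refer to that difference, not to levels in red cells. Top2a (2.05), Mki67 (1.61), the cyclin Ccna2 (1.34) and Cdk1 (1.18) passed of 14, and 8 adjusted over the list alone (camera adjusted p 8.0e-09, and adjusted p = 0.019 with an estimated correlation). These named genes were lower in red than green cells at E14.5 and did not pass at E18.5 (0.16, 0.44, 0.41 and -0.02). Camera called 7 further lists at the preset correlation. Immediate early and stress genes (median 0.35, adjusted p 9.9e-05, with Btg2 at 2.04) and neural progenitor genes (0.36, adjusted p 9.3e-04, with Olig3) had a higher difference at E18.5, with adjusted p = 0.106 and adjusted p = 0.223 with an estimated correlation. Neither Btg2 (0.54) nor Olig3 (-0.14) passed between red and green cells at E18.5. Thalamic transcription factors (-0.34, adjusted p 0.0011, with Prox1, a homeodomain factor, at -1.88), genes of glutamatergic transmission (-0.42, adjusted p 8.0e-04), ion channels (-0.15, adjusted p 8.0e-04), cadherins (-0.47, adjusted p 0.0028, with Cdh4 at -1.43, another transcript cluster of which differed between red and green cells by 0.25 at E14.5 and -0.17 at E18.5) and synaptic vesicle genes (-0.24, adjusted p 0.040) were lower. For these 5 lists adjusted p was 0.222, 0.112, 0.248, 0.553 and 0.528 with an estimated correlation, and synaptic vesicle genes had 0.070 at the preset correlation after quantile normalization. Adjusted over the list alone, 2 immediate early and stress genes were higher, 2 neural progenitor genes higher and 1 lower, 1 thalamic factor lower, 4 genes of glutamatergic transmission lower, 1 ion channel higher and 5 lower, 1 cadherin lower and 5 synaptic vesicle genes lower. Among other lists, Slit2 (2.20), Unc5c (1.15), a netrin receptor, and Slit1 (1.04) were higher and Flrt1 (-1.17) lower of 47 axon guidance genes, and Chrnb3 (1.70) was higher of 10 habenula genes. The other 14 lists had a camera adjusted p from 0.056 to 0.899, and immature neuron genes had a median of -0.05 and a mean of 0.06.

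**Figure D3:**
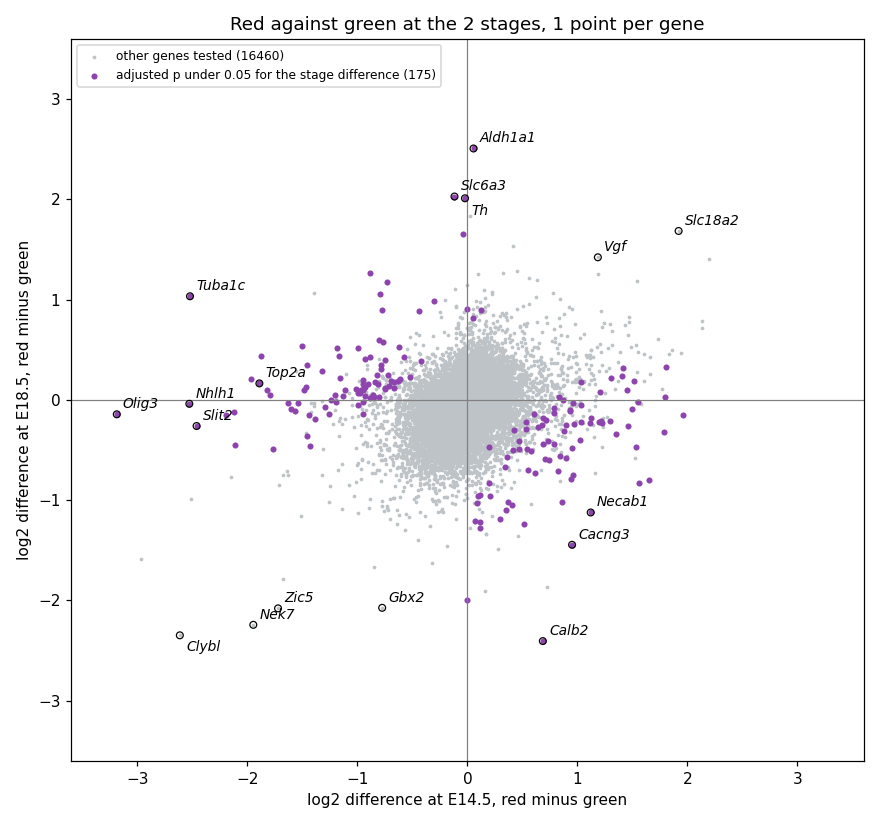
Log2 difference, red minus green, of each tested gene at E14.5 (x axis) and at E18.5 (y axis), from means of 3 arrays per group; purple points are the 175 genes whose differences differed between stages at adjusted p under 0.05, and the other points are the other tested genes. Olig3 lies at -3.19 at E14.5 and -0.14 at E18.5, and Calb2 at 0.69 and -2.41.

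Limma called 175 genes for a difference between stages, 91 higher and 84 lower at E18.5, 132 of them by at least 2-fold, and 1490 had an unadjusted p under 0.05. The count was 486 without the narrow-range arrays and, with single arrays left out, 109, 105 and 115 without E18.5 green replicates 1, 2 and 3, 114 and 99 without E14.5 red replicates 1 and 2, and 85 and 76 without E14.5 green replicates 2 and 3. Of the 23 named genes 18 kept their call whichever array was left out, and Tuba1c, Ccna2, Prox1, Slit1 and Mki67 lost theirs at least once, 5 without E14.5 green replicate 3, 4 each without E14.5 green replicate 2, E14.5 red replicate 2 and E18.5 green replicate 2, 3 each without E14.5 red replicate 1, E14.5 red replicate 3 and E18.5 green replicate 3, 2 each without E18.5 green replicate 1 and E18.5 red replicate 1, and 1 each without E14.5 green replicate 1, E18.5 red replicate 2 and E18.5 red replicate 3, at an adjusted p of at most 0.122. After quantile normalization Tuba1c (adjusted p 0.078) and Slit1 (0.093) no longer passed.

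Genes called at both stages overlapped more than independent calls would. Of 44 genes higher in E18.5 red cells, 9 were among the 314 higher in E14.5 red cells, where 0.831 would be expected (Fisher's exact test, adjusted p 4.3e-07 over 4 overlaps), among them Slc18a2 and Vgf. Of 58 genes higher in E18.5 green cells, 8 were among the 272 higher in E14.5 green cells, where 0.948 would be expected (adjusted p 8.7e-06), among them Lhx9, Zic5, Clybl and Nek7. Overlaps in opposite directions held 2 genes, Jam2 and Foxa1 (adjusted p 0.162), and 3 genes, Cacng3, Necab1 and Prkg1 (adjusted p 0.129). Genes are not independent replicates, and genes with small spreads pass more easily at both stages.

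Red cells at E18.5 were compared with red cells at E14.5 to ask which genes changed with age in the lineage. The arrays of the stages differ by a median of 0.60, tamoxifen was given on different days, and double-labelled cells were sorted apart only at E18.5. Age can therefore not be separated from scale, processing, labelling day or sort, and differences are given as deposited and after quantile normalization. Vsnl1, a neuronal calcium sensor, rose by 4.03 (from 5.95 ± 0.19 to 9.98 ± 0.82, n = 3, adjusted p 6.0e-07) and by 3.49 after quantile normalization. Cck rose by 3.56 (3.02), Aldh1a1 by 3.54 (3.02), Igfbp5 by 3.28 (2.78) and B2m, a component of class I histocompatibility molecules, by 3.13 (2.60). Lrp4, a low-density lipoprotein receptor family member, fell by 2.21 (from 8.42 ± 0.16 to 6.21 ± 0.40, adjusted p 7.3e-07; fell by 2.83), Crabp2, a retinoic acid binding protein, fell by 1.87 (fell by 2.41), Hbb-y fell by 1.36 (fell by 2.01) and the histone methyltransferase Ezh2 fell by 1.22 (fell by 1.78). Also higher at E18.5 were Mal2, Tspan17, Fxyd7, Dpp10 and Brinp3, by 3.10 to 3.70, and lower were Gng8, Kdm7a, Cdc14a, Zfp521, Phf21b and Rnf122, by -1.56 to -1.07. Gbx2 fell by 0.95 (adjusted p 0.012; fell by 1.59 after quantile normalization), while its other transcript cluster differed by -0.07.

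All 22 cadherins and protocadherins were higher at E18.5, 22 adjusted over the list alone and 17 after quantile normalization, with a median 0.96 above that of all genes (camera adjusted p 0.0073, and adjusted p = 0.513 with an estimated correlation), among them Cdh7 (2.83) and Cdh13 (1.70). Of 18 synaptic vesicle genes 17 were higher, 17 adjusted over the list alone and 13 after quantile normalization, with a median 0.46 above that of all genes (camera adjusted p 0.0020, and adjusted p = 0.494 with an estimated correlation), among them Syn2 (2.27) and Syt1 (1.96). Of 27 ion channels 23 were higher, 23 adjusted over the list alone and 8 after quantile normalization (camera adjusted p 0.043, and adjusted p = 0.494 with an estimated correlation), among them Kcnd2 (2.06) and Kcnq3 (1.53). Of 13 genes of glutamatergic transmission 12 were higher and 3 after quantile normalization, among them Grm5 (2.05) and Gria4 (1.77), and camera did not call the list (adjusted p 0.170). Camera called thalamic transcription factors (adjusted p 0.0011), immature neuron (7.4e-04), neural progenitor (0.047), axon guidance (0.042) and sex-linked genes (0.019) lower relative to all genes, with adjusted p = 0.220 for thalamic, immature neuron and sex-linked genes, 0.494 for progenitors and 0.513 for axon guidance with an estimated correlation. Their medians lay -0.37, -0.44, -0.12, -0.01 and -0.46 from that of all genes, while the medians themselves were above 0. Rorb (1.15), a nuclear receptor of thalamic neurons, rose all the same. Of 16 thalamic factors 6 were higher and 2 lower, 4 and 2 adjusted over the list alone, and 1 and 5 after quantile normalization. The counts were 6 higher and 2 lower of 15 immature neuron genes, 8 and 2 of 15 progenitor genes (8 and 1 adjusted over the list alone), and 27 and 2 of 47 axon guidance genes (26 and 2). Of 4 sex-linked genes 0 passed. Camera called 8 lists, 4 after quantile normalization and 5 each without E18.5 red replicate 2 and E14.5 red replicate 1. The other 14 lists had an adjusted p from 0.167 to 0.664. The sign of the median differed from camera's direction or the mean in 9 lists, each with a direction set relative to all genes.

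Limma called 12041 genes between the stages in red cells, 98.5% of them higher at E18.5, and 4538 genes, 48.5% of them higher, after quantile normalization. Groups did not overlap for 73.1% of all genes as deposited, where chance gives 10%, but the shift between stages raises this share by itself. All 30 named genes kept their call whichever array was left out, and 2638 of the 12041 were also called after quantile normalization.

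Green cells were compared between the stages with the same question and the same limits, and their arrays differed by a median of 0.61. Vsnl1 rose by 5.04 (from 5.01 ± 0.14 to 10.04 ± 0.16, n = 3, adjusted p 4.7e-08) and by 4.32 after quantile normalization, and Calb2 rose by 4.47 (from 5.46 ± 0.12 to 9.93 ± 0.32, adjusted p 2.4e-09) and by 3.73. Necab1 rose by 4.17 (3.44), the calcium-binding protein S100a10 by 4.23 (3.49) and Gabrg1, a GABA-A receptor subunit, by 3.93 (3.20). Olig3 fell by 3.48 (from 8.93 ± 0.29 to 5.45 ± 0.30, adjusted p 1.1e-08; fell by 3.98), Nhlh1 fell by 2.51 (fell by 3.04), Tuba1c fell by 3.36 (fell by 3.89) and Rspo3 fell by 2.24 (fell by 2.80). Also higher at E18.5 were Brinp3, Mal2, Gyg, Syne1 and Kctd12, by 3.83 to 4.26, and lower were Pantr1, Phf21b, Kdm7a, Jam2, the actin-binding protein Cnn3 and Pou3f2, by -3.02 to -1.94. Gbx2 stood 0.35 higher at E18.5 (adjusted p 0.296). Other transcript clusters differed by 0.50 to 3.46 for Syne1, 1.41 for Kctd12 and -2.25 for Tuba1c.

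Cell cycle genes fell in green cells relative to all genes. Of 14 tested, 5 were lower and 3 higher as deposited, 5 and 2 adjusted over the list alone, and 10 lower and 0 higher after quantile normalization, where the group median was -0.76 (camera adjusted p 1.9e-10, and adjusted p = 0.010 with an estimated correlation). Mki67 (-1.28), Top2a (-1.23) and Cdk1 (-1.18) were among them. Camera also called neural progenitor genes (adjusted p 2.0e-04, with the proneural factor Neurog2 at -1.18) and immature neuron genes (8.2e-04, with Igfbpl1 at -1.45) lower, with adjusted p = 0.205 and adjusted p = 0.20 with an estimated correlation. As deposited 6 progenitor genes were higher and 3 lower, and 8 immature neuron genes higher and 4 lower, with the same counts adjusted over the list alone, and after quantile normalization 0 and 8, and 4 and 7. All 22 cadherins and protocadherins rose, 22 adjusted over the list alone and 18 after quantile normalization, among them Pcdh10 (2.40) and Cdh4 (2.19, and 0.60 in another transcript cluster). Of 27 ion channels 25 rose, 26 adjusted over the list alone and 15 after quantile normalization, among them Kcnd2 (3.40) and Hcn3 (2.16). Of 18 synaptic vesicle genes 17 rose, 17 adjusted over the list alone and 11 after quantile normalization, among them Syn2 (3.73) and Syt1 (2.56). Of 13 genes of glutamatergic transmission 11 rose, 12 adjusted over the list alone and 6 after quantile normalization, among them Grm5 (3.67) and Gria4 (2.61). Camera called these 4 lists higher with adjusted p 3.0e-04, 8.2e-04, 8.2e-04 and 0.014, and adjusted p = 0.425, 0.251, 0.270 and 0.251 with an estimated correlation. Prox1 (2.52) and Rorb (1.78) rose among thalamic transcription factors, a list camera did not call (adjusted p 0.501). The other 15 lists had an adjusted p from 0.060 to 0.884. The sign of the median differed from camera's direction or the mean in 8 lists, each with a direction set relative to all genes.

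Limma called 12226 genes between the stages in green cells, 96.7% of them higher at E18.5, and 5589 genes, 46.4% of them higher, after quantile normalization. Groups did not overlap for 85.5% of all genes as deposited, where chance gives 10%, but here too the shift between stages raises this share by itself. All 35 named genes past the threshold kept their call whichever array was left out, and 3304 of the 12226 were also called after quantile normalization.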

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

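Of the tests below, the slope and spread of the narrow-range arrays, their cell-type lists as deposited, the markers of radial glia and the counts of splits and regroupings that part pairs were chosen after the result was seen. Limma's test of the difference between stages singled out 175 genes whose red-green difference was not the same at E18.5 and E14.5. Of 100 drawn regroupings within each stage, the real grouping included, 2 gave as many genes, the highest other 422. That share is under the 0.05 set in advance. Since another regrouping gave more genes than the real one, chance is made less likely for the number of genes but not excluded. As many lists as the 8 that camera called came from 10 of 100 regroupings, the highest other 11, so chance is not excluded for the number of lists.

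Among the genes named in the text, 37 differed between stages, as a higher or lower log2 difference of red from green at E18.5. The difference was higher for Tuba1c (3.55), Olig3 (3.04), Nhlh1 (2.49), Aldh1a1 (2.45), Pou3f2 (2.32), Slit2 (2.20), Jam2 (2.15), Slc6a3 (2.14), Top2a (2.05), Abcd2 (2.04), Btg2 (2.04), Th (2.03), Ube2c (2.01), Foxa1 (1.91), Chrnb3 (1.70), Mki67 (1.61), Ccna2 (1.34), Cdk1 (1.18), Unc5c (1.15) and Slit1 (1.04). It was lower for Calb2 (-3.09), Ripor2 (-2.45), Cacng3 (-2.40), Mast4 (-2.39), Necab1 (-2.24), Kitl (-2.11), Lrfn5 (-2.10), Ldb2 (-2.0), Prox1 (-1.88), Rbfox1 (-1.77), Trpm3 (-1.48), Syn2 (-1.45), Cdh4 (-1.43), Cacna1e (-1.42), Hbb-y (-1.36), Flrt1 (-1.17) and Grin2b (-1.08). Camera also called lists for a red-green difference that differed between stages. It was higher at E18.5 for cell cycle (median 0.66), neural progenitors (0.36) and immediate early and stress genes (0.35). It was lower at E18.5 for cadherins (-0.47), glutamatergic transmission (-0.42), thalamic transcription factors (-0.34), synaptic vesicle (-0.24) and ion channels (-0.15). With an estimated correlation the cell cycle list alone was still called (adjusted p = 0.019), and the other 7 had adjusted p from 0.106 to 0.553.

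Th, Slc6a3 and Aldh1a1 were higher in E18.5 red than in green and double-labelled cells. The tables argue against the narrow-range arrays as the source, since without them the smallest of the 6 differences kept was 0.871 of its size. Midbrain dopamine neurons among the red cells may bring these genes, yet the median of 14 markers listed before the test was 0.389, between the bound that would have excluded them and the one that would have met the prediction. Of the 14, 9 were above 0.3 and 4 under 0.3 in size, Ddc (0.88) and Foxa1 (1.18, at 6.79 in red cells) passed, En1 (0.87), Dlk1 (0.65), Lmx1a (0.60), Sncg (0.54), En2 (0.43), Lmx1b (0.34) and Foxa2 (0.34) were higher without passing, and Drd2 (-0.79) was lower without passing, Foxa1 also standing in the list of hypothalamus, pretectum and zona limitans. The 4 under 0.3 were Gch1 (0.2997), Ret (0.15), Pitx3 (0.12) and Slc10a4 (0.03). Outside the 14, Slc18a2 (1.68) and Nr4a2 were also higher in red than in green cells, though Slc18a2 did not pass against double-labelled cells. The sort by colour would remove midbrain dopamine neurons only if they lacked tdTomato, and a red-labelled thalamic population that expresses Th, Slc6a3 and Aldh1a1 remains an untested alternative.

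Cell cycle genes, Olig3, Nhlh1 and Neurod1 were higher in E14.5 green than red cells. Green cells may lie earlier than red cells on the axis from E14.5 to E18.5: across 16635 genes, which are not independent replicates, the red-green difference at E14.5 correlated with the mean change between stages at r 0.420 (0.393 after quantile normalization, rho 0.359), the largest size in the 9 other groupings being 0.354. Radial glia among the green cells, at a median of 0.018 over 10 markers, cannot be told apart from this, because 5 markers were higher and 5 lower in red cells, and a median near 0 over members that go both ways decides nothing. The 3 markers above the median gene in green cells, Nes (-0.54), Vim (-0.45) and Fabp7 (-1.40), all stood higher in green cells. Their median was -0.54, with Nes alone past the threshold. The other markers stood at 4.65 to 5.46 in green cells, near the floor, and weigh little against them. Among those, Slc1a3 (1.01, at 5.66 in red cells) was higher in red cells and passed. All but Aldoc and Sox9 of these 10 also stand in the list of neural progenitors, and the sort on EGFP would keep such cells where the Gbx2 locus is active.

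E18.5 red replicate 1 and double-labelled replicate 1 had a narrower range of values than the other 7 E18.5 arrays. The tables argue against a large share of RNA from the 11 other cell types listed, since no list median reached the 0.5 set in advance in both arrays. After the trend with level was removed the highest was 0.0870 (oligodendrocyte lineage, 0.220 in the red array), and as deposited, where a narrow range alone lifts weakly expressed genes, that list stood 0.371 and 0.273 above group mates. As deposited, all the other lists but GABAergic and prethalamic neurons (0.102 and -0.0158) were also raised in both. Examples are meninges (0.208 and 0.304), hypothalamus (0.217 and 0.299), neural progenitors (0.132 and 0.178) and microglia (0.115 and 0.259). A small share, or a cell type not listed, stays open. An exchange of the labels of the 2 arrays is excluded by their places at 1.02 and 0.302 on the axis from double-labelled to red cells over 39 genes. A compressed signal from a weaker amplification may account for them: their deviations from group mates fell with level, with slopes of -0.188 and -0.237 against -0.0373 to 0.113 in the others. A narrow range gives such a slope by itself, and after the trend was removed the spread in pairs with them was still 0.445 to 0.509 against 0.226 to 0.286 in other pairs, so this cannot be told apart from further differences between the samples. Beyond RNA from other cell types, no biological explanation was tested, as the labels give none for these arrays.

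For each comparison of 3 with 3 arrays, 10 splits cannot give a share under 0.05. Gene counts in the real split and the highest other were 102 and 1 for E18.5 red against green, 6 and 1 for double-labelled against green, 15 and 2229 for double-labelled against red, 586 and 0 at E14.5, 12041 and 0 between stages in red, and 12226 and 0 in green cells, with 1, 1, 3, 1, 1 and 1 splits as large as the real one. List counts in the same order were 5 and 9, 6 and 7, 1 and 8, 7 and 7, 8 and 7, and 7 and 8, with 2, 2, 8, 2, 1 and 2 splits as large. The splits with 2229 and 1185 genes put the narrow-range arrays on one side with red replicate 3 or red replicate 2, which points to a structure of the samples. The numbers pair red with double-labelled arrays, and among the splits that part all 3 pairs the real one gave 15 genes and the others 0, 0 and 0. This subset was chosen after the counts were seen and leaves out both splits with more genes. It is also too small to exclude chance.

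Of 100 regroupings drawn from the 280 of the 9 E18.5 arrays, 11 gave as many genes in the F test as the real 71, the highest other 2363, and 11 gave as many population-enriched genes as the real 18, the highest other 884, so chance is not excluded by the share of all 100. The regroupings differ in how they treat the red and double-labelled arrays that the numbers pair. Among the 51 that part all 3 pairs, as the real grouping does, the real one alone gave as many genes, the next giving 18 in the F test and 14 population-enriched. This subset was chosen after the counts were seen and leaves out every other regrouping as large, so it does not exclude chance for either count. The other 49 put at least 1 pair in one group and held all 10 regroupings as large as the real one. The narrow-range arrays, which form 1 of these pairs, shared a group in 22, with up to 2363 genes, a structure of the samples.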

How the results depend on the processing

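The settings that left out the narrow-range arrays, gave 1 weight per stage or used E18.5 arrays alone were chosen after seeing the data. Across settings, 170 counts of genes or lists stayed within 1.5 times the reported count and 100 did not. Named genes kept their side of the threshold 3221 times, fell out of it 331 times and came into it 20 times. Reversals of direction were counted only where the gene passed in either fit, and there were 0. Changes of sign where it passed in neither are among the 3221. Arrays give signal over a background that varies by probe, so values near the floor are compressed, and 3 arrays per group limit what passes. A pseudocount was not run, as the values are log2 already, and the array weights did not converge, with a weight of 14.1 on double-labelled replicate 3.

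In the order E18.5 red against green, double-labelled against green, double-labelled against red, any difference, population-enriched genes, E14.5 red against green and the difference between stages, the reported gene counts were 102, 6, 15, 71, 18, 586 and 175. Array weights gave 206, 1110, 446, 1394, 353, 2523 and 644. Fitting the compared arrays alone gave 6, 0, 0, 6, 4, 1367 and 312, and the cause is the spread, which then comes from fewer arrays or from 1 stage. Leaving out the narrow-range arrays gave 213, 35, 39, 206, 45, 1434 and 486. With replicate number as a block the first 5 were 234, 12, 32, 152 and 38, and the difference between stages 343. With 1 weight per stage the first 6 were 44, 0, 8, 16, 8 and 1703. With E18.5 arrays alone and the narrow-range arrays left out the first 5 were 46, 0, 0, 21 and 0, and with the 9 E18.5 arrays the first 3 were 12, 0 and 4. At least 2-fold left 46 genes for E18.5 red against green, 39 for any difference and 173 at E14.5. Quantile normalization gave 32 for double-labelled against red. Beside the counts of 0, limma had 949 genes (double-labelled against green) and 752 (against red) at unadjusted p under 0.05 as reported. By chance a share of 0.05 of the 16635 genes would have such a p. Apart from the spread in fits to fewer arrays, the cause of the changes in count was not tested.

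Between stages, red and green cells gave 12041 and 12226 genes as reported, 7059 and 7589 with genes below the median left out (fewer genes tested), 4538 and 5589 after quantile normalization, 3861 and 5501 after centring each array on its median (both remove the shift between stages), and 2443 and 3244 at 2-fold.

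Lists called, in the order E18.5 red against green, double-labelled against green, double-labelled against red, E14.5 red against green, red stages, green stages and difference between stages, were 5, 6, 1, 7, 8, 7 and 8 as reported and 0, 0, 0, 3, 0, 1 and 1 with an estimated correlation. Quantile normalization gave 0 for double-labelled against green and 4 for red stages. Leaving out the narrow-range arrays gave 3 for E18.5 red against green and 0 for double-labelled against green.

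With each array left out in turn, gene counts ranged from 51 to 100 for E18.5 red against green, 0 to 8 for double-labelled against green, 7 to 21 for double-labelled against red, 17 to 166 for any difference, 7 to 25 for population-enriched genes, 247 to 527 at E14.5 and 76 to 214 for the difference between stages. List counts ranged from 4 to 8 for E18.5 red against green, 2 to 7 for double-labelled against green, 1 to 3 for double-labelled against red and 5 to 7 for red stages. The lowest gene counts came without E18.5 green replicate 1 (51 and 17), E18.5 green replicate 3 (0), double-labelled replicate 2 (7 and 7), and E14.5 green replicate 3 (247 and 76).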

Other observations

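The genes in this part were chosen after their values were seen, and no test here was planned. Further genes kept their direction at both stages between red and green cells. Higher in red cells at E18.5 and E14.5 were the serotonin receptor Htr1b (log2 difference 0.93 and 0.93), the lymphangiogenic factor Vegfc (1.01 and 0.84), Zdhhc22 (1.26 and 1.18) and Ebf1 (1.19 and 0.63). Higher in green cells at both stages were the homeodomain factor Shox2 (-0.85 and -1.71), the nuclear factor Nfib (-1.16 and -1.52) and the corepressor Tle3 (-1.08 and -0.73). After quantile normalization Ebf1 and Tle3 no longer passed at E14.5 (limma adjusted p 0.062 and 0.074), nor Nfib at E18.5 (0.054). Across all 16635 genes, which are not independent replicates, the red-green differences of the stages correlated at r 0.290 (rho 0.319).

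Gt(ROSA)26Sor, the transcript of the locus that carries the tdTomato reporter, stood at 7.80 ± 0.49 in E18.5 red, 7.68 ± 0.30 in double-labelled and 6.96 ± 0.22 in green cells (mean ± SD, n = 3), and at 6.78 ± 0.26 in E14.5 red and 6.44 ± 0.14 in E14.5 green cells. At E18.5 its difference from green cells was 0.84 in red cells (limma adjusted p 0.166) and 0.72 in double-labelled cells (adjusted p 0.611). Without the narrow-range arrays these were 1.13 (adjusted p 0.0024) and 0.90 (adjusted p 0.042).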
